A study of Homo sapiens with 6 samples.

How the data were processed

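Gene expression was measured in clones of the HCA-7 colorectal cancer cell line grown in type 1 collagen, a cystic and a spiky clone, at day 5, 10 and 15, with 1 Affymetrix U133 Plus 2.0 array per clone and day. The deposited values are on the log2 scale and come from RMA, per the submitters' processing notes; its version and settings are not given in the sources used here. Per the labels, biotin-labelled cRNA was prepared from total RNA of the cell-containing collagen layer. The values run from 1.72 to 15.07, array medians lie between 5.18 and 5.34, and 0 values are missing. Arrays carry no read depth, and their number limits the precision.

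Probe sets were named through the platform's gene table, with symbols updated by gene ID to the RefSeq gene table of assembly GRCh38.p14. Of 54675 probe sets 41097 had 1 gene symbol, 1801 several and 11777 none, and 41043 of the named ones matched the RefSeq table (54 kept the platform's symbol). The genome build behind the platform's table is not given in the sources used here, so no coordinates are printed and the RefSeq table served for names, chromosomes and which genes neighbour each other. Each of 19775 genes was represented by its single-symbol probe set with the highest mean, and 12317 genes with a mean log2 of at least 5 were tested. For 923 of these the chosen probe set ends in _x_at, a type that can detect related genes, CXCL2 and TGM2 included. For some genes with several probe sets, GJC1, SEMA3A, EPHA4 and PTPRO among them, only the chosen one reached that mean.

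Groups, the planned comparisons, the rules for naming genes, 23 gene lists and 3 marker lists were fixed before the data were examined; tests and names added later are given as such. Linear models were fitted in limma 3.58.1 (R 4.3.3) to all 6 arrays with culture day as a factor and colony shape, and with moderated variances that followed the intensity trend; this left 2 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A model with day as a number and its interaction with colony shape gave the slope difference per 10 days. Gene lists with at least 5 tested genes were tested with limma's camera at an inter-gene correlation of 0.01, with an estimated correlation and with fry as alternatives. Camera compares the genes of a list with all other tested genes, so its higher and lower are relative to those genes. Day was kept as a block because it is a factor of the design. Deviations from the group means correlated at 0.608, 0.496 and 0.719 (across genes) between the arrays of day 5, 10 and 15, and at -0.65 to 0.291 between different days. The deviations of a clone cancel over its days, so positive values within days pull those between days down. This contrast is therefore partly built in. Figures were drawn with matplotlib 3.10.9, and principal components were computed in R.

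The genes named were the 10 highest and 10 lowest differences that passed with the same sign at all 3 days, for culture day the 8 highest and 8 lowest with the same sign in both clones, and for the slope, where 0 passed, the 5 largest in each direction among genes whose day 10 value lay between those of day 5 and 15 in both clones. Log2 differences are as fitted; where an array of the dimmer group lay under log2 5, the fold is a lower bound that sets such arrays to 5. Per list, the 2 rising and 2 falling genes with the smallest p were named, or the largest differences where none passed, together with 14 genes fixed in advance; symbols that start with LOC or hold orf were skipped. PDK1, VEGFA, MCM2 and the interferon receptor genes were added after their values were seen, as were genes whose place on a chromosome or low count called for a name.

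The fit was tested on simulated data with 200 of 12317 genes changed. For spiky against cystic it recovered 14.5%, 76.4% and 98.5% of genes changed by log2 0.5, 1 and 2, with 3.01% false calls, and for day 15 against day 5 it recovered 6.06%, 41.0% and 94.5%, with 3.92% false calls. For the slope difference it recovered 0%, 4.55% and 26.2%, with change linear in day and noise taken from the fit with day as a factor. In each comparison the noise was independent between genes and arrays and followed the variance model that limma assumes. The low share of false calls is thus built in and does not test the model on the real arrays. Recovery also depends on the share of genes changed, and the real comparisons called 11.4% (spiky against cystic) and 32.3% (day 15 against day 5). In 20 simulations without list effects camera called at most 1 list. This does not settle how camera behaves on lists whose genes vary together. The antigen presentation list had an estimated correlation of 0.42 for spiky against cystic. Splits of the arrays other than the real one still called 3 to 10 lists. Alternatives covered the filter on dim genes, the probe set per gene, array scaling, the variance prior, culture day in the model, the unit tested, the set test and leaving out each array, and those added later are named in the closing section. 0 columns of other samples were present. The fibroblast, leukocyte and endothelial markers had median levels of 3.51, 4.29 and 4.02, and 0 of the 6 tested were called between spiky and cystic colonies; between day 15 and day 5 COL1A1 (1.38) and ESAM (-0.65) were called.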

Results

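HCA-7 is an established human colorectal cancer cell line that grows in collagen gels as cystic or as spiky colonies. A clone of each shape was cultured in type 1 collagen, and total RNA from the cell-containing layer of the gel was measured on Affymetrix U133 Plus 2.0 arrays at day 5, 10 and 15. The 6 arrays thus comprised 3 cystic and 3 spiky samples, with 1 array per clone and day. Each colony shape was represented by 1 clone, so differences between spiky and cystic colonies cannot be told apart from differences between the clones. The culture days of 1 clone each served as the replicates, and nothing in the labels says that they were separate cultures, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision of every value. Array medians lay between 5.18 and 5.34 on the log2 scale.

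Culture time and clone, and with it colony shape, separated the arrays along different axes. The first principal component of the 12317 tested genes held 48.0% of the variance and set both day 15 arrays, at 38.1 and 38.1, apart from the other arrays, at -33.0 to -8.70. The second component held 30.1% and set the cystic arrays, at 16.1 to 27.0, apart from the spiky arrays, at -26.2 to -15.6.

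**Figure D1:**
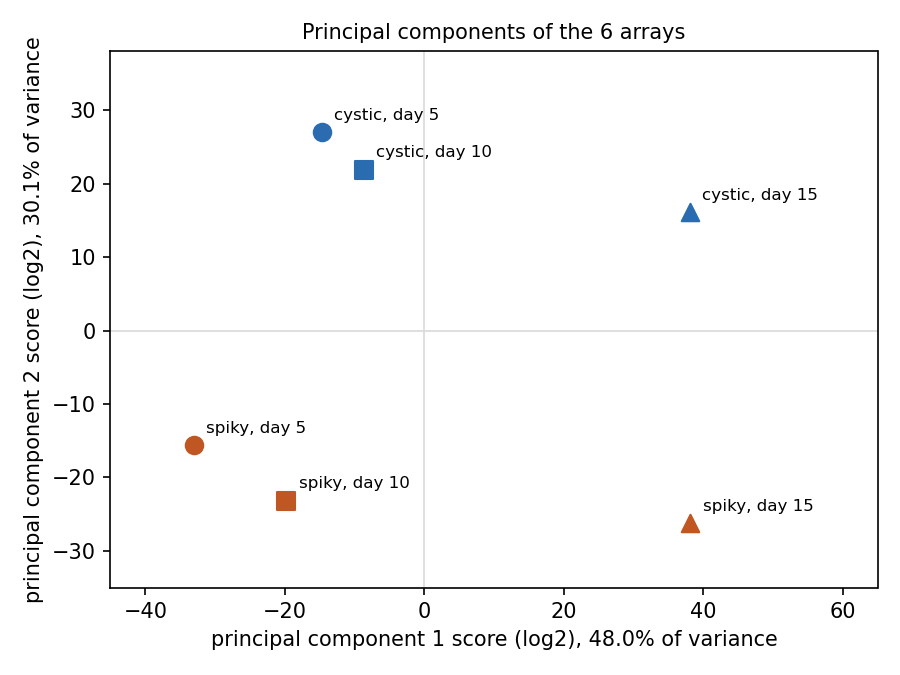
Scores of the 6 arrays on the first principal component (48.0% of variance, horizontal axis) and the second (30.1%, vertical axis), in log2 units; colour gives the colony shape, the symbol gives the day. Both day 15 arrays lie at 38.1 on the horizontal axis, and the cystic arrays lie at 16.1 or higher on the vertical axis.

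The comparison of spiky with cystic colonies asked which genes differ between the clones across the culture. VCAN, which encodes the large matrix proteoglycan versican, showed the largest fitted difference, with 9.19 ± 0.49 in spiky and 4.03 ± 0.24 in cystic colonies (log2, mean ± SD, n = 3). Because levels under log2 5 are close to background, folds against them are given as lower bounds, which for VCAN is at least 18.3-fold higher; 3 of 3 other bright VCAN probe sets had the same sign. The connexin gene GJC1 was at least 8.63-fold higher in spiky colonies (log2 difference 4.82, SE 0.27), and RASGRF2, an exchange factor for Ras family proteins, at least 6.18-fold higher. HPGD, the enzyme that starts prostaglandin breakdown, was at least 4.58-fold lower (log2 difference -3.81, SE 0.35), and the neutrophil-attracting chemokines CXCL1, CXCL3 and CXCL2 were 10.6-fold, 9.06-fold and at least 6.89-fold lower. In limma with Benjamini-Hochberg adjustment these genes had adjusted p from 7.5e-06 for VCAN to 0.000748 for CXCL1.

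The other genes with the highest fitted differences were PLAC8 (8.72-fold), the secreted dickkopf protein DKK3 (8.45-fold), the zinc finger transcription factor MECOM (at least 3.91-fold) and PPP1R14A, an inhibitor of myosin phosphatase (at least 5.24-fold). CYP24A1, which inactivates vitamin D, was at least 3.71-fold, the carboxypeptidase CPA4 at least 3.70-fold and the junctional scaffold MPDZ at least 2.32-fold higher. The lowest fitted difference was that of NUDT11, at 4.16 ± 0.18 against 8.17 ± 0.25 (at least 8.98-fold). The secreted guidance protein SEMA3A was 10.7-fold, the ephrin ligand EFNB2 at least 5.28-fold, NELL2 at least 4.58-fold, ZNF544 8.19-fold and GALNT12, an enzyme that starts mucin-type O-glycosylation, at least 5.74-fold lower.

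**Figure D2:**
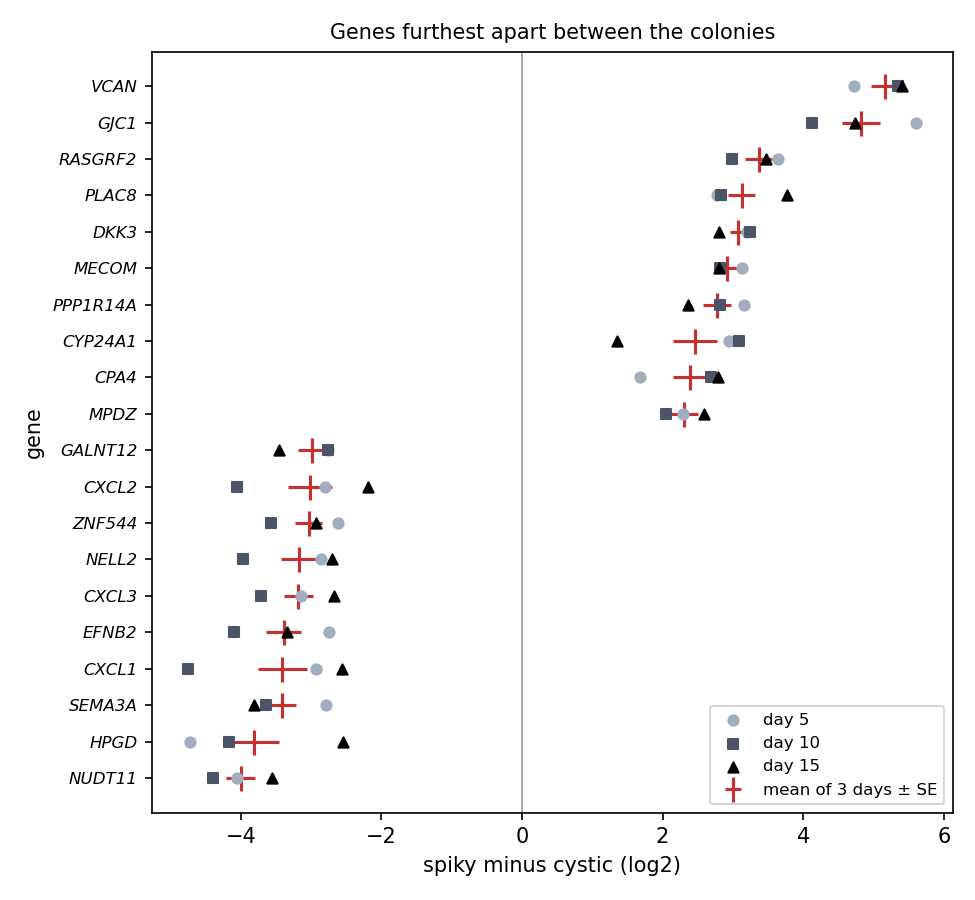
Spiky minus cystic difference (log2, horizontal axis) at day 5, 10 and 15 for the 10 genes furthest above and the 10 furthest below 0 (vertical axis), with the mean of the 3 days ± SE in red. VCAN lies furthest to the right at 5.16 and NUDT11 furthest to the left at -4.00; the HPGD difference was -4.72 at day 5 and -2.55 at day 15.

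The NF-kB and chemokine, antigen presentation and interferon response lists were called lower in spiky colonies by camera at a fixed correlation of 0.01, and each had adjusted p = 0.429 with an estimated correlation. Of 26 tested NF-kB and chemokine genes 15 fell and 1 rose (18 and 1 adjusted over the list alone), with a median of -0.80; CXCL8 was 5.01-fold lower and CXCL3 9.06-fold lower, whereas PIGR, the epithelial carrier of secreted immunoglobulin, rose by 1.86. The list was called lower by camera with adjusted p = 8.8e-08. Of 19 antigen presentation genes 9 fell and 0 rose (12 and 0 adjusted over the list alone), and all 19 had negative values, among them HLA-DRA at -1.80 (at least 2.21-fold lower) and the invariant chain gene CD74 at -1.10; the list had adjusted p = 2.9e-07. Of 30 interferon response genes 11 fell and 0 rose (13 and 2 adjusted over the list alone), and the antiviral GTPase genes MX1 and MX2, both on chromosome 21, were at least 4.76-fold and 2.63-fold lower. That list had a median of -0.51 with adjusted p = 3.5e-05. The medians of the 3 lists were -0.77, -0.57 and -0.70 at day 5, -0.96, -0.68 and -0.57 at day 10, and -0.34, -0.18 and -0.16 at day 15. The leukocyte marker genes, most of them below the level required for testing, had a median difference of -0.04. The 3 tested were all lower in spiky colonies, CSF1R at -0.93, CORO1A at -0.58 and CD3D at -0.10. Limma called 0 of them, and CSF1R had the smallest adjusted p, at 0.0652.

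In the goblet, integrin, matrix and prostaglandin lists more genes passed as lower than as higher. Of 15 goblet and secretory genes 6 fell and 0 rose (7 and 0 adjusted over the list alone), led by GALNT12 and the transmembrane mucin MUC1, which was at least 6.47-fold lower. Of 18 integrin genes 6 fell and 1 rose (9 and 1 adjusted over the list alone): ITGB7 was at -1.54, ITGA5, part of the fibronectin receptor, at -0.74, and ITGA6, part of laminin receptors, at 0.24. Among 20 matrix remodelling and invasion genes 6 fell and 2 rose (10 and 2 adjusted over the list alone); the matrix protease MMP7 was 5.57-fold lower and the protease inhibitor SERPINE2 was at -1.73, while VCAN and the actin bundler FSCN1, at 1.30, rose. Of 15 prostaglandin genes 6 fell and 1 rose (8 and 1 adjusted over the list alone), with HPGD and the transporter SLCO3A1 (-1.59, at least 2.64-fold) lower, thromboxane synthase TBXAS1 (0.86) higher and the inducible cyclooxygenase PTGS2 at -0.87 (SE 0.12, limma adjusted p = 0.00233). Camera called these lists lower with adjusted p = 0.000146, 0.000388, 0.00245 and 0.00274, and each had adjusted p = 0.429 with an estimated correlation. In the same order the list medians were -0.83, -0.49, -0.35 and -0.24 at day 5 and -0.64, -0.43, -0.41 and -0.52 at day 10. At day 15 they were -0.10, -0.42, -0.19 and -0.08.

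MAPK transcriptional output was the list called higher by camera, with adjusted p = 0.00294, but 0.429 with an estimated correlation. Of its 25 genes 5 rose and 3 fell (7 and 4 adjusted over the list alone): the MAPK phosphatase DUSP4 at 1.43 and the immediate early gene EGR1 at 0.55 were higher, and EPHA4 at -1.08 and DUSP6 at -0.44 lower. In the unfolded protein and amino acid stress list 3 of 26 genes fell and 0 rose (7 and 1 adjusted over the list alone), among them PHGDH at -1.34 and PSAT1 at -0.87, both enzymes of serine synthesis. Camera called this list lower with adjusted p = 0.0177, and it had adjusted p = 0.429 with an estimated correlation.

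The receptor genes MET, MST1R (which encodes RON), EGFR, ERBB2 and ERBB3 did not pass. Their differences were 0.14, 0.18, 0.01, -0.20 and -0.02, with SE from 0.09 to 0.16 and limma adjusted p from 0.322 to 0.974. Of 19 MET and RON axis genes 2 rose and 3 fell (2 and 3 adjusted over the list alone), with CD44, a hyaluronan receptor, at 1.03 in the same sense in 12 of 12 other bright probe sets, SEMA4D at -1.01 and the protease gene PLAU at -1.53. In the EGFR family and ligands list 1 of 13 rose, the feedback inhibitor ERRFI1 at 0.65, and 1 fell, the ligand EREG at -0.95 with adjusted p = 0.0241 (1 and 1 adjusted over the list alone); TGFA was at -0.30 with adjusted p = 0.190 and no probe set was named AREG alone. CDH1, which encodes E-cadherin, was at -0.37 (adjusted p = 0.0653) and MKI67 at 0.13 (adjusted p = 0.580). VIM, at 4.26 in spiky and 4.07 in cystic colonies, and LGR5, at 3.90 and 3.02, were below the level required for testing.

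The remaining lists were not called by camera. Among 30 epithelial adhesion and polarity genes the tight junction gene CGN rose (0.78) and the desmosomal cadherin DSC2 fell (-0.81; 1 and 1 adjusted over the list alone). Of 13 mesenchymal and EMT genes VCAN rose and 3 fell (1 and 3 adjusted over the list alone), including S100A4 at -1.78 and CTHRC1 at -1.51; the mean of this list was 0.07 while its median was -0.12 and the test pointed down. Of 20 WNT target and stem cell genes 2 rose, CD44 and the WNT inhibitor DKK1 (1.84), and 3 fell, among them PTPRO (-0.21) and ETS2 (-0.72, on chromosome 21). Adjustment over the list alone gave 3 and 3. The PTPRO probe set had means of 13.1 in spiky and 13.3 in cystic colonies, while none of the gene's other probe sets reached a mean of log2 5. Among 25 TGF-beta and YAP targets 3 rose, including BMP4 (1.22) and CRIM1 (0.75), and 3 fell, including TGFBR1 (-0.93) and BAMBI (-1.09; 4 and 4 adjusted over the list alone). Of 40 cell cycle genes TOP2A (0.55) and CDCA7 (0.89) rose and 3 fell, including CCNE2 (-1.38) and RRM2 (-0.34; 2 and 5 adjusted over the list alone). Of 27 hypoxia and glycolysis genes HK2 (0.89) and MXI1 (0.57) rose and the glucose transporter SLC2A1 (-1.19) fell, and adjustment over the list alone gave 2 and 1.

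Of 17 epithelial ion and water transport genes the chloride channel CFTR rose (1.12) and 3 fell, among them AQP3 (-0.62) and KCNN4 (-0.82; 1 and 4 adjusted over the list alone). ALDH1A1 (2.11) and TXNRD1 (0.40) rose and GPX2 (-0.87) fell among 20 metallothionein and oxidative stress genes (2 and 2 adjusted over the list alone). UGT1A6 (1.77) rose and CYP4F2 (-0.64) fell among 16 xenobiotic metabolism and transporter genes (1 and 1 adjusted over the list alone). The enterocyte gene VIL1 (-0.68) fell and 0 of 8 in its list rose (2 and 0 adjusted over the list alone), LSS (-1.19, on chromosome 21) fell and 0 of 18 cholesterol synthesis genes rose (1 and 0 adjusted over the list alone), and CPE (-0.78, at least 1.69-fold) fell among 3 enteroendocrine genes, too few for the list test (1 and 0 adjusted over the list alone). For the epithelial list the mean was -0.01 and the median -0.02 while the test pointed up.

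Genes of chromosomes 13 and 21 were lower together in spiky colonies, in a grouping by chromosome that was not among the planned comparisons. The median difference was -0.69 over 201 chromosome 13 genes and -0.59 over 137 chromosome 21 genes, whereas the medians of the other 21 chromosomes lay between -0.18 and 0.07. Of the chromosome 13 genes 128 fell and 0 rose, and of the chromosome 21 genes 89 fell and 0 rose. Together they made up 217 of 953 lower calls (22.8%) but 2.74% of the tested genes. The medians were -0.59, -0.79 and -0.66 at day 5, 10 and 15 on chromosome 13, and -0.48, -0.66 and -0.57 on chromosome 21. EFNB2 lies on chromosome 13. Parts of chromosomes 9, 15 and 19 held runs of neighbouring genes that were shifted together, with medians from -0.58 to 0.71. MPDZ lies in the run with higher values, from FOXD4 to NOL6 on chromosome 9, and ZNF544, GALNT12, SLCO3A1, PSAT1 and TGFBR1 lie in runs with lower values. AQP3 lies where the higher run overlaps a lower one, from IFT74 to TMEM8B.

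**Figure D3:**
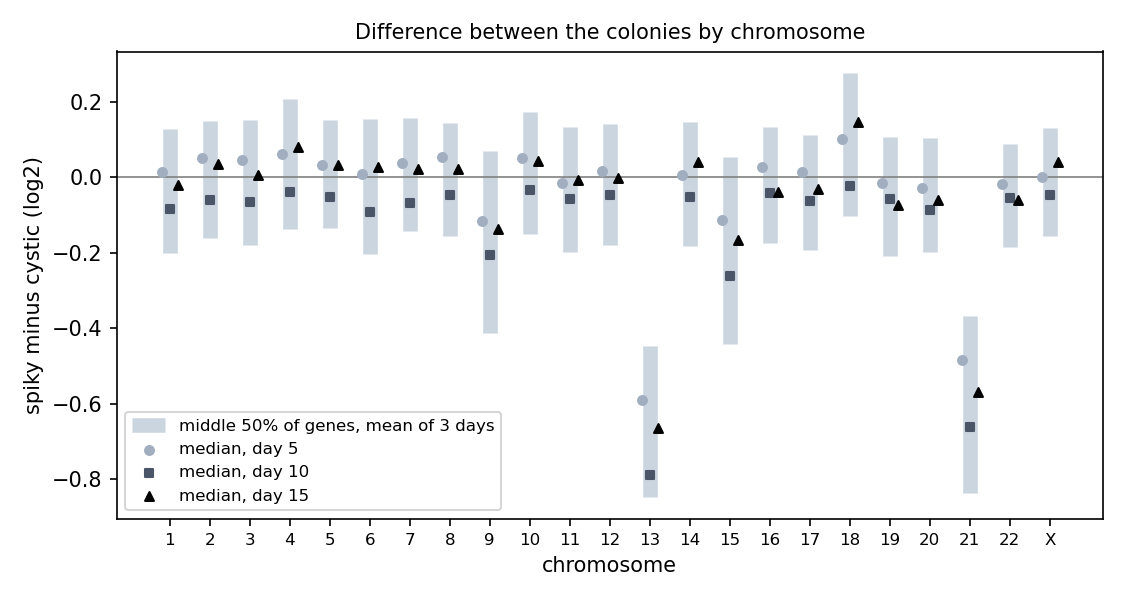
Spiky minus cystic difference (log2, vertical axis) of the tested genes of each chromosome (horizontal axis); bars run from the first to the third quartile of genes for the mean of the 3 days and symbols give the median at each day. Chromosomes 13 and 21 have medians between -0.79 and -0.48 at every day, below the bars of all other chromosomes.

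In all, limma with Benjamini-Hochberg adjustment called 1405 of 12317 genes, 452 higher and 953 lower in spiky colonies, of which 347 differed at least 2-fold (102 higher, 245 lower). Of the calls, 1404 had the same sign at all 3 days, the exception being TMSB4X, and 45.0% of all tested genes did so against 25% by chance. The difference in 3' over 5' signal of the ACTB control probe sets served as a sign of RNA integrity. It was 2.83, 3.18 and 3.28 (log2) on the cystic and 2.73, 2.74 and 3.10 on the spiky arrays at day 5, 10 and 15. For GAPDH it was 0.65, 0.79 and 0.63 on the cystic and 0.60, 0.63 and 0.49 on the spiky arrays. Without culture day as a block in the model 72 genes were called, and with any 1 array left out 509 to 2157. With each array centred on its median, 1446 genes were called, 643 higher and 803 lower (55.5% lower against 67.8%).

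The comparison of day 15 with day 5 asked what changed in both clones over the culture. At a fixed correlation of 0.01 camera called the hypoxia and glycolysis list higher and the cell cycle list lower, and with an estimated correlation both had adjusted p = 0.545. DKK4, a secreted WNT inhibitor, showed the largest fitted rise, from 5.50 at day 5 through 6.31 at day 10 to 10.74 at day 15 (log2, means of 2 arrays), which is at least 31.2-fold (SE of the log2 difference 0.23, limma adjusted p = 3.6e-05); it rose by 4.80 in cystic and by 5.68 in spiky colonies. CYP1A1, a target of the aryl hydrocarbon receptor, fell by 3.47, and the matricellular YAP target CCN2 fell by 2.52 on the log2 scale.

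The membrane protein gene PROM2 was at least 12.0-fold, the myoglobin gene MB at least 8.70-fold, the monoamine and nucleoside transporter SLC29A4 10.3-fold and the antisense RNA gene LMNTD2-AS1 at least 7.39-fold higher at day 15. DDIT4, an inhibitor of mTOR signalling induced by hypoxia, was 8.47-fold, PPFIA4 8.31-fold and transglutaminase TGM2 at least 7.84-fold higher. Among the genes with the lowest fitted differences were those for EFNB2 (at least 2.92-fold lower), AMIGO2 (at least 3.72-fold), the endothelin gene EDN1 (at least 4.54-fold), PIGW (4.72-fold), GPAT3 (at least 3.83-fold) and DDIAS (at least 4.27-fold). CYP1A1 already differed at day 10, by -2.66 from day 5.

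Of 27 hypoxia and glycolysis genes 21 rose and 0 fell (22 and 0 adjusted over the list alone), with a median of 1.01. NDRG1 was at 2.54 (SE 0.12, adjusted p = 3.6e-05), the prolyl hydroxylase subunit gene P4HA1 at 1.66, the pyruvate dehydrogenase kinase PDK1 at 2.02 and VEGFA, the vascular growth factor, at 1.52. Camera called the list higher with adjusted p = 1.7e-16, and it had adjusted p = 0.545 with an estimated correlation. Of 40 cell cycle genes 35 fell and 0 rose (37 and 0 adjusted over the list alone), with a median of -0.68; GINS2 was at -1.60, the ribonucleotide reductase subunit RRM2 at -1.13, the replicative helicase subunit MCM2 at -1.17 and MKI67 at -0.65. This list had adjusted p = 2.4e-11, and adjusted p = 0.545 with an estimated correlation. Both clones moved alike: the medians of the hypoxia list were 0.91 in cystic and 1.21 in spiky colonies, and those of the cell cycle list -0.65 and -0.74. The ACTB 3' over 5' difference rose beside these lists. It went from 2.83 at day 5 to 3.28 at day 15 in cystic and from 2.73 to 3.10 in spiky colonies. That of GAPDH did not rise, at 0.65 and 0.63 in cystic and 0.60 and 0.49 in spiky colonies. The fibroblast collagen gene COL1A1 rose by 1.38 (limma adjusted p = 0.00203). FBLN1, the other fibroblast marker tested, was at 0.21 (adjusted p = 0.487). The remaining fibroblast markers were below the level required for testing.

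**Figure D4:**
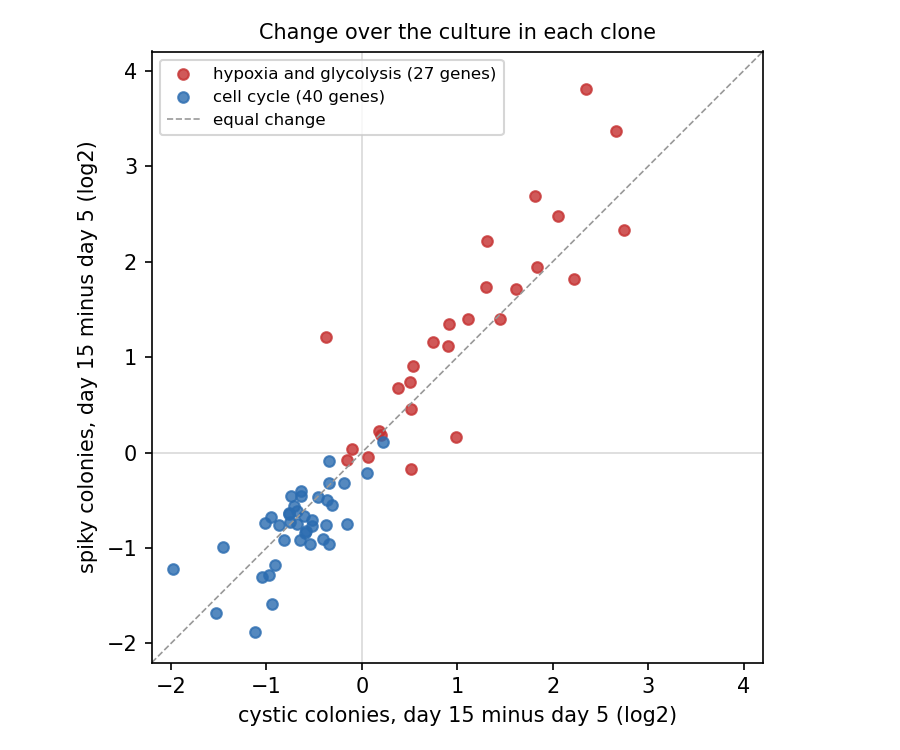
Day 15 minus day 5 difference (log2) in cystic (horizontal axis) and spiky (vertical axis) colonies for the 27 hypoxia and glycolysis genes and the 40 cell cycle genes; each point is a gene and the dashed line marks equal change. Hypoxia genes have medians of 0.91 and 1.21, cell cycle genes of -0.65 and -0.74.

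Camera called the amino acid and unfolded protein stress list lower at day 15. Of its 26 genes 10 fell and 0 rose (12 and 0 adjusted over the list alone), among them PSAT1 at -1.55 and the amino acid transporter SLC7A5 at -1.51, with adjusted p = 0.0341, and adjusted p = 0.545 with an estimated correlation; with cyclic loess between arrays the call was lost (adjusted p = 0.103). Of 15 goblet and secretory genes 6 rose and 2 fell (6 and 2 adjusted over the list alone), with the mucin MUC4 at 1.58 and AGR2 at 0.96 against KLF4 at -1.02 and FOXA3 at -0.71. In the matrix remodelling and invasion list 5 of 20 rose and 0 fell (5 and 0 adjusted over the list alone), including tissue plasminogen activator PLAT at 2.18 and the hyaluronan-degrading protein CEMIP at 1.81. Of 19 MET and RON axis genes 3 rose and 0 fell (2 and 0 adjusted over the list alone), SEMA4D at 1.17 and MST1, the RON ligand, at 1.10 among them. These 3 lists had adjusted p = 0.0111, 0.00243 and 0.0181, and each had adjusted p = 0.545 with an estimated correlation. Of 19 antigen presentation genes 7 rose and 2 fell (8 and 2 adjusted over the list alone): HLA-E at 0.67 and TAPBP at 0.53 were higher, and TAP2 at -0.58 and PSMB10 at -0.87 lower. This list had adjusted p = 0.00243, and adjusted p = 0.711 with an estimated correlation.

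In most lists that camera did not call, members moved in both directions. Of 26 NF-kB and chemokine genes 7 rose and 2 fell (7 and 2 adjusted over the list alone), with PIGR at 2.82 and the antimicrobial lipocalin LCN2 at 1.91 against CXCL8 at -1.59 and IL32 at -1.30. Of 30 interferon response genes 7 rose and 4 fell (7 and 4 adjusted over the list alone), with IRF9 at 1.85 and MX2 at 1.18 against HERC6 at -0.88 and IFIT5 at -0.94. Of 20 WNT target and stem cell genes 4 rose and 2 fell (4 and 2 adjusted over the list alone), with APCDD1 at 2.38 (at least 3.71-fold) and SP5 at 1.46 against DKK1 at -1.60 and MYC at -0.46. Of 25 TGF-beta and YAP targets 2 rose, ID1 at 1.18 and SKIL at 0.83, and 6 fell (3 and 6 adjusted over the list alone), including PMEPA1 at -1.89 and the tissue factor gene F3 at -1.40. Of 17 epithelial ion and water transport genes 5 rose and 1 fell (5 and 1 adjusted over the list alone), with the sodium channel subunit SCNN1A at 2.22 and CFTR at 0.77 against ATP1B3 at -0.35. Of 16 xenobiotic metabolism and transporter genes CYP3A5 rose (2.24) and 7 fell (4 and 7 adjusted over the list alone), among them CYP1A1 and GSTP1 (-0.95).

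Of 30 epithelial adhesion and polarity genes 3 rose, the claudin CLDN2 at 2.27 and TJP3 at 1.21 among them, and 6 fell, including KRT18 at -0.66 and MARVELD2 at -0.75 (3 and 6 adjusted over the list alone); CDH1 was at 0.32 with adjusted p = 0.104. Of 13 mesenchymal and EMT genes S100A4 (0.89) and COL6A1 (0.63) rose and THBS1 (-1.92, at least 3.46-fold) and MSN (-0.72, but 0.15 with adjusted p = 0.576 with the mean of its probe sets) fell (2 and 2 adjusted over the list alone), and VCAN was at 0.63 with adjusted p = 0.0658. Among 25 MAPK output genes 7 rose, including FOS at 2.27 and EGR1 at 1.58, and 5 fell, including DUSP4 at -1.10 and FOSL1 at -1.07 (7 and 5 adjusted over the list alone). Of 13 EGFR family genes 3 rose, ERBB3 at 0.90 and the sheddase ADAM10 at 0.51 among them, and 3 fell, including TGFA at -0.86 and EGFR at -0.76 (3 and 3 adjusted over the list alone). EREG was at -1.17 with adjusted p = 0.0105, but its 1 other bright probe set had the opposite sign. MET, MST1R and ERBB2 did not pass, with adjusted p = 0.771, 0.999 and 0.281.

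Of 18 integrin genes 4 rose and 3 fell (4 and 3 adjusted over the list alone), with ITGA1 at 1.68 (at least 2.79-fold) and FERMT1 at 0.63 against ITGB1BP1 at -1.04 and FERMT2 at -0.71. The cyclooxygenase PTGS1 (2.02) and PLA2G4A (0.66) were among 3 of 15 prostaglandin genes that rose, ABCC4 (-0.96) and CBR1 (-0.71) among 3 that fell (3 and 3 adjusted over the list alone), and PTGS2 was at 0.33 with adjusted p = 0.107. AKR1C1 (0.86) and MT1F (0.45) were among 5 of 20 metallothionein and oxidative stress genes that rose, and GCLM (-1.89) and TXNRD1 (-0.95) among 8 that fell (6 and 8 adjusted over the list alone). STARD4 (1.10) rose and ACAT2 (-0.69) and TMEM97 (-0.62) were among 3 of 18 cholesterol synthesis genes that fell (1 and 3 adjusted over the list alone). The glucose cotransporter SLC5A1 (1.57, at least 2.70-fold) rose and 0 of 8 enterocyte genes fell (1 and 0 adjusted over the list alone), and 0 of 3 enteroendocrine genes passed, CPE at 0.34 and SCGN at -0.28 showing the largest differences. For the EGFR, TGF-beta and YAP and metallothionein lists the mean and median were below 0 while the test pointed up, for the EMT list too, and for the epithelial, MAPK, prostaglandin, cholesterol and ion transport lists only the median was below 0. Camera's direction is relative to the other genes, and the median of all tested genes was -0.11 in this comparison.

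In all, limma with Benjamini-Hochberg adjustment called 3982 genes between day 15 and day 5, 1287 higher and 2695 lower (2-fold or more: 428 and 527), and 75.5% of all tested genes changed with the same sign in both clones against 50% by chance. Between day 10 and day 5 it called 2 genes, CYP1A1 and MROH1 (1.62, adjusted p = 0.0146), named after their values were seen, with 1658 genes at an unadjusted p under 0.05. Between day 15 and day 10 it called 2787 genes, 1068 higher and 1719 lower. For both of these steps only values were planned, so their calls were added. With each array centred on its median, 4521 genes were called between day 15 and day 5, 1069 higher and 3452 lower (76.4% lower). With cyclic loess between arrays 3739 genes were called, 1680 higher and 2059 lower (55.1% lower against 67.7%), and without the spiky day 5 array 766.

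The last comparison asked whether the clones changed differently over time. Limma called 0 genes for a difference in slope, with 309 at an unadjusted p under 0.05 against 616 by chance and a smallest adjusted p of 0.999. Among genes whose day 10 value lay between those of day 5 and 15 in both clones, the largest fitted values, which did not pass, were found for LRATD1, at 2.55 per 10 days (3.43 to 6.56 in spiky and 6.16 to 6.74 in cystic colonies from day 5 to day 15), and TMEM158, at -3.01 (6.84 to 4.96 and 5.08 to 6.20). The transcription factor RUNX3 (2.54), PROM2 (2.42), the LIM protein AJUBA (2.33) and SEMA3F (2.12) had the next highest values, and FAM3B (-2.26), SLC25A2 (-1.77), ZNF575 (-1.69) and FBXO36 (-1.66) the next lowest. Of the 2 other bright RUNX3 probe sets only 1 had the same sign. With values under log2 5, close to background, set to 5, LRATD1 had 0.99, PROM2 1.51, RUNX3 2.46, SLC25A2 -1.30, ZNF575 -1.53, FBXO36 -1.39 and TMEM158 -2.96, so the order of these genes depends on dim values. Tested on simulated data for this comparison, 26.2% of genes with a slope difference of log2 2 were recovered. The simulated noise came from the fit with day as a factor, and the simulated change was linear in day. Shared changes that are not linear in day widen the spread of the real slope fit, so recovery there may be lower. Without the spiky day 5 array 31 genes were called, and without the spiky day 10 array 1, ATOH8 (4.21, adjusted p = 0.00872), named after its value was seen; with all arrays it also had 4.21, with adjusted p = 0.999, and its day 10 value did not lie between those of the other days.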

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

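The tests of shuffled genes, of scaling by cyclic loess alone and of leukocyte markers, the interferon list without chromosomes 13 and 21, the reading of day 10 against day 5, and the look at interferon receptors were chosen after the results were seen. The test of gene lists for the slope difference, the grouping of genes by chromosome and the calls between day 15 and day 10 were not among the planned comparisons. TGF-beta and YAP targets changed more upward in spiky than in cystic colonies by camera's test of the slope difference, with a mean of 0.702 per 10 days (adjusted p = 2.4e-07, but 0.846 with an estimated correlation; 20 of 25 genes above 0), and the list's median spiky minus cystic difference was -0.04 at day 5, -0.14 at day 10 and 0.72 at day 15, so the change rests on the day 15 arrays. The same test called the cholesterol synthesis (0.448), epithelial adhesion and polarity (0.334), antigen presentation (0.333), interferon response (0.443), mesenchymal and EMT (0.415) and goblet and secretory lists (0.459), with adjusted p from 0.000322 to 0.0409, but 0.846 for each with an estimated correlation. Limma called 0 genes of these 7 lists, with 309 of all genes at an unadjusted p under 0.05.

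The 6 arrays can be split into 3 and 3 in 10 ways, so the share of splits as large as the real one cannot be under 0.05. For spiky against cystic the real split called 1405 genes and the highest other split 0, so 1 of the 10 reached the real value. For gene lists the real split called 9 and the highest other 10, with 3 splits at 9 or more. Like the real split, some others part the arrays of all 3 days. These called 8, 7 and 3 lists and 0 genes. The remaining 6 keep the arrays of a day together, and with day in the model they give the same result in pairs. The splits at 10 lists are such a pair. In all splits but the real one the difference between the clones adds to the residual spread, which works against gene calls. For the slope difference all 10 splits gave 0 genes, the real value and the highest other being 0.

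Genes of chromosomes 13 and 21 were lower in spiky colonies at every day. In 0 of 10000 shuffles of genes over chromosomes did any chromosome reach a median of -0.593 (one-sided permutation p = 1e-04, the smallest they can give; the shuffles treat genes as independent), which argues against chance clustering of lower genes. A change with culture day that both clones share cancels in this difference by design. Under cyclic loess both medians stayed at -0.566 or lower relative to all genes. Such scaling treats genes of like intensity alike whatever their chromosome, so this outcome was largely fixed in advance. Lower dosage of both chromosomes in the spiky clone is a candidate explanation: with genes split by expression level into low, middle and high, the medians of both chromosomes were below 0 at each level, the one nearest to 0 being -0.369. This remains a hypothesis from the same arrays, since DNA copy number was not analysed here.

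The NF-kB, antigen presentation and interferon lists were called lower in spiky colonies at a fixed correlation of 0.01, but each had adjusted p = 0.429 with an estimated one. The NF-kB and antigen presentation lists have 0 tested members on chromosomes 13 and 21; such members do not account for the whole of the interferon list's shift, because without MX1 and MX2 its median was still -0.44, with adjusted p = 0.000136 at the fixed and 0.399 at an estimated correlation. Leukocyte RNA in the cystic arrays cannot be told apart, since the markers' median of -0.0375 lay over members that went both ways (SD 0.44). Most of these markers were close to background, with means over the arrays of 2.95 for PTPRC, 2.82 for CD3E and 3.05 for MS4A1. Those tested were CSF1R (5.63), CORO1A (5.44) and CD3D (5.18), all lower in spiky colonies. The labels name no cells other than the cell line. The interferon receptor subunits IFNAR1, IFNAR2, IFNGR2 and IL10RB, all on chromosome 21, were at -0.77, -1.04, -0.73 and -1.18 (limma adjusted p from 0.00231 to 0.0241), while IFNGR1 on chromosome 6 was at 0.22 (adjusted p = 0.243).

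The rise of hypoxia genes and the fall of cell cycle genes at day 15 came with a rise in the ACTB 3' over 5' difference. The GAPDH difference did not rise, at 0.65 and 0.63 on the cystic and 0.60 and 0.49 on the spiky arrays of day 5 and 15. With the ACTB difference as a covariate the hypoxia list kept 83.6% and the cell cycle list 94.1% of its mean. Both stayed called at a fixed correlation of 0.01. The model also held culture day and clone, so the effect of the covariate was estimated only from variation left after these. It therefore cannot decide whether RNA quality, read this way, caused the shift in their means. With an estimated correlation neither list was called without the covariate (adjusted p = 0.545) or with it (0.793), and single genes called fell from 3982 to 6, with 1 residual degree of freedom fewer. Arrays processed in batches by culture day cannot be told apart from culture time, since each day holds 1 array per clone; day 10 against day 5 called 2 genes.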

How the results depend on the processing

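The alternatives that leave out both arrays of a day, leave out chromosomes 13 and 21, or set day 15 against days 5 and 10 were chosen after the data were seen. Spiky against cystic (1405 genes) gave 1094 to 1446 under the filters, probe set choices, scalings and robust prior, 1111 without chromosomes 13 and 21, 347 at a log2 difference of at least 1, 691 with no intensity trend, 566 with day as a number and 2709 of 29412 when every probe set was tested. Without the replicate block, that is with no pairing by day, 72 genes and 8 lists were called. Leaving out 1 array gave 509 to 2157: 521 and 509 without the cystic or spiky day 5 array, 786 and 787 without day 10, and 2157 and 2153 without day 15; leaving out both arrays of day 5, 10 or 15 gave 498, 779 and 2171; an array left alone on its day adds nothing to this contrast. Day 15 against day 5 (3982) gave 3001 to 4521 elsewhere, 955 at a log2 difference of at least 1, 2162 with day as a number, and 766 (without spiky day 5) to 4318 with 1 array left out (2220 without cystic day 5). The slope difference stayed at 0, except 31 without spiky day 5 and 1 without spiky day 10 (range 0 to 31); day 15 minus day 5 alone equals it by construction. Of the lists, 9 (spiky against cystic) and 7 (day) were called; 0 and 0 with an estimated correlation, 1 and 3 by fry in 1 direction, 18 and 20 in either direction, and for day 4 with the most variable probe set and 4 with a mean of at least 7. Leaving out 1 array gave 9 to 11 and 5 to 10 lists. MSN reversed for day 15 against day 5 with the mean of its probe sets (0.15, adjusted p = 0.576). Where construction does not show it, the cause was not tested. Of the named genes called, 23 of 76 (spiky against cystic) and 49 of 89 (day) were called in every planned setting, and 0 of the lists. Genes below a mean log2 of 5, 7458 in all, are close to background and were not tested.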

Other observations

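The runs of neighbouring genes outside chromosomes 13 and 21 were looked for after the chromosome pattern was seen. In windows of 31 neighbouring genes with a median of at least 0.4 in either direction, 6 runs on 3 chromosomes were found, 5 lower and 1 higher in spiky colonies, against 0 in 100 shuffles of gene order. The higher run, from FOXD4 to NOL6 on chromosome 9, held 54 genes with a median of 0.71, of which 31 rose and 9 fell. The longest lower run, from TLE3 to TARS3 on chromosome 15, held 169 genes with a median of -0.44, of which 81 fell. The run from ZNF784 to CENPBD2P on chromosome 19 held 41 genes with a median of -0.58. The other lower runs were on chromosome 9 and had medians of -0.40, -0.40 and -0.42. The lower runs held 186 lower calls. ALDH1A1, higher by 2.11, lies inside the lower run from ZCCHC7 to NAA35.

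Among probe sets with no gene symbol, 4300 passed the level filter when each probe set was tested alone, and limma with Benjamini-Hochberg adjustment called 279 of them between spiky and cystic colonies, 106 higher and 173 lower.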
